A study of Mus musculus with 15 samples.

How the data were processed

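Gene expression was measured in gonadal white adipose tissue of male mice, 7 wild type and 8 Sfrp5 knockout, with 1 Affymetrix mouse gene array per mouse. Per the labels' protocols, total RNA was extracted, amplified and labelled with biotin from nanogram amounts with a whole-transcript kit. Genotype and replicate number were taken from the submitters' sample labels.

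The deposited values are log2 expression values per probe set, 35557 probe sets in 15 arrays, which the authors made by RMA, per the submitters' processing notes. RMA corrects background, makes the distributions of the arrays alike and summarises the probes of a set, so a shift common to most genes is removed before deposit. Whether it was run on all 15 arrays together is not given in the sources used here, and quantile normalization of the deposited values ended 5 of the 8 list calls, so differences in distribution between arrays may remain in the list differences. The processing notes also name limma, affy 1.18 and Affymetrix Expression Console 1.1.2800.19935, with no role or order. The genome build and the annotation version behind the probe sets are not given in the sources used here. Scanner files were not used here, so background and detection per probe could not be assessed, and no depth applies to arrays: their number limits the precision.

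Probe sets were named through the platform annotation. Exactly 1 gene symbol was given for 21789 probe sets, several for 1621 and none for 12147; no gene was named from a probe set of the last 2 kinds. Of the 21789 gene identifiers, 21698 matched the RefSeq gene table of GRCm38.p6, which gave current symbols, the chromosome and the order of genes and no printed coordinate. A gene was represented by its brightest probe set over all 15 arrays, giving 19938 named genes. Of these, 999 had more than 1 probe set, and in 381 of them the probe sets differed in sign.

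Knockout and wild-type arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate) on the deposited log2 values, with no filter on dim probe sets. The p-values were adjusted by Benjamini-Hochberg over all 35557 probe sets, with a threshold of 0.05. Control probe sets were not identified or left out, so they may be among the probe sets without a symbol. SEs of genes are moderated by limma. Sfrp5 was also tested by an exact permutation of the genotype labels. The gene lists, 27 with 587 entries of which 548 were measured, were fixed before the data were examined, as were the main tests, the rule for named genes and the other settings tried, apart from those named as later choices. Lists with at least 5 measured genes, 26 of the 27, were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the lists. None of the 8 calls at the preset correlation held with an estimated correlation. The SE of a list is that of the difference between the genotypes' means of the list mean per array. The position of genes was tested with Fisher's exact test on the 100 named genes with the lowest p, since fewer than 20 named genes passed, against the 19919 named genes with a chromosome.

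The genes named are Sfrp5, the 12 with the lowest p on each side, leaving out predicted genes without an official name, the 3 with the lowest p in each list, and a fixed set of 13 genes whatever their p. The alternatives were another normalization, a filter that left out probe sets under the 33rd percentile of mean level, another variance model, array weights, other thresholds, other list tests, the mean of a gene's probe sets, arrays left out, and the replicate number as a block.

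The submitters' array descriptions give each array a position from 1 to 15, with the wild-type arrays at positions 1 to 7 and the knockout arrays after them, so if arrays were handled in that order, order and genotype cannot be told apart. The descriptions also give a number whose meaning is not stated; it is 640 or higher in all wild-type arrays and in knockout replicates 7 and 8, and lower in the other knockout arrays.

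The fit and the list test were tested on simulated data with 35557 probe sets in 7 and 8 arrays, in which 200 probe sets were shifted. At a log2 shift of 0.3 the fit recovered 32% of 50 probe sets, at 0.5 it recovered 64%, at 1 it recovered 88% and at 1.5 it recovered 100%. There were 4 false calls. The adjusted threshold is easier to pass where many probe sets are shifted. These shares may therefore be too high for the real arrays, where 12 probe sets passed. With no list raised camera called 0 lists, but the simulated genes vary independently, so this does not give its false calls in the real arrays, where other splits of the arrays called a median of 7 lists. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.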

Results

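Gonadal white adipose tissue, the fat pad that lies along the epididymis of male mice, was profiled in 7 wild-type and 8 Sfrp5 knockout mice on a C57BL6/J background. Sfrp5 encodes secreted frizzled-related protein 5, an extracellular protein that binds Wnt ligands and is made by adipocytes. The knockout allele carries a premature stop codon in the coding sequence. All mice had eaten a high-fat diet for 8 weeks, starting at 4 weeks of age, when tissue was taken at 12 weeks. The comparison asks how loss of Sfrp5 alters transcript levels in this depot during diet-induced expansion of fat. Each mouse contributed 1 array, with 35557 probe sets per array and values on the log2 scale. Array medians lay between 6.99 and 7.07, and correlations between pairs of arrays lay between 0.963 and 0.987 across probe sets. The number of arrays limits the precision of every value below.

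Sfrp5 itself was lower in the knockout tissue, as its probe set (10467744) read 7.92 ± 0.24 (SD, n = 7) in wild-type and 6.69 ± 0.40 (SD, n = 8) in knockout arrays. The log2 difference, knockout minus wild type, was -1.23 (SE 0.16), a 2.35-fold lower signal, with limma's Benjamini-Hochberg adjusted p = 0.0200. The ranges did not overlap, from 7.66 to 8.33 in wild type and from 6.02 to 7.12 in the knockout. An exact two-sided permutation test over all 6435 splits of the arrays gave p = 0.000155, the smallest value it can give. A stop codon need not lower a transcript, and where the probes lie relative to it was not analysed here, so the signal checks the labels without measuring the protein. Sfrp5 passed the threshold in 8 of the 15 fits that left out 1 array. Its adjusted p was 0.0520, 0.0517, 0.0600 and 0.0533 without wild-type replicates 2, 3, 4 and 5, and 0.0670, 0.0501 and 0.0517 without knockout replicates 2, 5 and 8. It was 0.3001 with the replicate number as a block, 0.119 without wild-type replicate 4 and knockout replicate 2 together, and 0.316 with replicates 7 and 8 as the only knockout arrays, where the difference was -0.93.

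**Figure D1:**
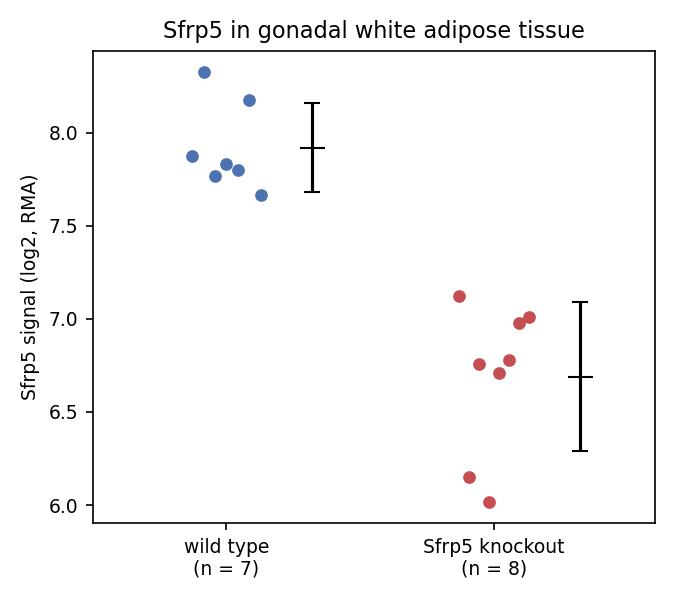
Sfrp5 signal on the log2 scale (vertical axis) in each of 7 wild-type and 8 knockout arrays, with the mean and SD of each genotype beside its points. All knockout arrays, from 6.02 to 7.12, lie below all wild-type arrays, from 7.66 to 8.33.

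Beyond Sfrp5, the named gene past the threshold was Zfp971, a zinc-finger gene, which rose by a log2 difference of 0.52 (SE 0.08; limma adjusted p = 0.0390) and lay above the wild-type mean in 8 of 8 knockout arrays. In all, 12 of 35557 probe sets passed, 10 higher and 2 lower in the knockout, and 10 of these 12 carry no gene symbol in the annotation used. Among the unnamed ones, probe set 10597511 was higher by 0.85 (SE 0.14) and 10364091 by 0.72 (SE 0.10), while 10338532 was lower by a log2 difference of -0.48 (SE 0.08). What the unnamed ones measure was not analysed here, and some may be control probe sets, which were not identified or left out. At an unadjusted p below 0.05 there were 3544 probe sets, 1757 higher and 1787 lower, where chance gives 1778 on average. Where probe sets vary together, a count can lie far from that average by chance. Its spread over other splits of the arrays was not measured at this threshold. The count of 12 became 0 without any 1 of wild-type replicates 2, 3, 4 and 5 or knockout replicates 2, 5 and 8 (with 3003 to 3521 at an unadjusted p below 0.05), 32 without wild-type replicate 6 and 133 without knockout replicate 1, and lay between 2 and 8 without any other array. It was 6 with quantile normalization, 7 with median centring, 26 with dim probe sets left out, 48 with an intensity trend and robust prior and 25 with array weights. It was 2 without knockout replicates 7 and 8, and limma called 0 with these as the only knockout arrays (3392 at an unadjusted p below 0.05) and 0 with the replicate number as a block (3098). Zfp971 passed in 2 of the 15 fits with 1 array left out, those without wild-type replicate 6 (adjusted p = 0.0233) and without knockout replicate 1 (adjusted p = 0.00450), with up to 0.123 in the others. It also missed the threshold with quantile normalization (adjusted p = 0.0512), median centring (0.0536), the replicate number as a block (0.3001), replicates 7 and 8 as the only knockout arrays (0.316), without these 2 arrays (0.173), and without wild-type replicate 4 and knockout replicate 2 together (0.172). With limma's p adjusted over named genes alone, Zfp971 missed it as well (adjusted p = 0.109).

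The named genes with the next lowest p-values did not pass. On the higher side, As3mt, an arsenic methyltransferase, differed by 0.44 (SE 0.08; limma adjusted p = 0.0693). Slc44a1, a choline transporter, differed by 0.28, Pyroxd2, an oxidoreductase, by 0.32, and ND3, a complex I subunit encoded by mitochondrial DNA, by 0.33. Prdx1, a peroxiredoxin that reduces peroxides, differed by 0.30, Hk1, a hexokinase, by 0.25, and Snrpe, a core spliceosomal protein, by 0.25. Ceacam16 (0.34), Snord95 (0.41), the pseudogene Anp32-ps (0.45) and Tcim (0.25) complete this side, where adjusted p ranged up to 0.128. On the lower side, Arhgap19 differed by -0.53 (SE 0.10; limma adjusted p = 0.0867). Tlr6, a Toll-like receptor of macrophages and other immune cells, differed by -0.70, Syt14 by -0.59, Cutc, a protein of copper handling, by -0.34, and the relaxin gene Rln1 by -0.32. The taste receptor Tas2r108 (-0.40), the vomeronasal receptors Vmn1r185 (-0.35) and Vmn1r216 (-0.38), the olfactory receptor Olfr270 (-0.31) and the microRNA genes Mir672 (-0.35) and Mir541 (-0.33) were also listed. Those 6 genes had mean levels between the 2.86th and the 23.5th percentile of named genes, so their signals were dim, and adjusted p on the lower side ranged up to 0.119.

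Nuclear-encoded subunits of oxidative phosphorylation, the respiratory chain and ATP synthase, were higher in the knockout for 58 of 73 measured genes. The mean log2 difference of the list was 0.06 (SE 0.03 over arrays), and camera, limma's test of a list against other genes, gave adjusted p = 5.84e-09. With an estimated correlation between genes the adjusted p was 0.872. After quantile normalization of the deposited values the mean was 0.01 (SE 0.03), with 38 of 73 genes higher and adjusted p = 0.310. With replicates 7 and 8 as the only knockout arrays the adjusted p was 0.391. None of the 73 passed alone, whereas 11 had an unadjusted p below 0.05, each of them higher. Atp5l, an ATP synthase subunit, differed by 0.20 (SE 0.05), Uqcrb of complex III by 0.20 (SE 0.06) and Cox7b of complex IV by 0.16 (SE 0.05). The regulators of mitochondrial biogenesis were split, 11 higher and 8 lower of 19 (camera adjusted p = 0.688). Ppargc1a, the coactivator that drives mitochondrial gene expression, differed by 0.08 (SE 0.23), Tfam, which maintains mitochondrial DNA, by 0.09 (SE 0.10), Polg by -0.15, Gabpa by 0.15 and Mfn2 by -0.15. Of 17 genes of the tricarboxylic acid cycle 9 were higher (adjusted p = 0.688), with Idh2 at -0.08, Dld at 0.09 and Pdhb at 0.12. Of 22 genes of fatty acid oxidation 10 were higher (adjusted p = 0.695), with Etfa at 0.11, Acaa1a at -0.11 and Acaa2 at -0.12. The tricarboxylic acid list had a mean of -0.00 but a median of 0.02, and camera placed it, like fatty acid oxidation and insulin signalling, on the higher side although their means lay just below 0.

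Genes of fatty acid and triglyceride synthesis were higher for 15 of 21 measured members, with a mean log2 difference of 0.07 (SE 0.07; camera adjusted p = 0.00633, and adjusted p = 0.872 with an estimated correlation). Scd1, the stearoyl-CoA desaturase of fat and liver, differed by 0.21 (SE 0.05) and lay above the wild-type mean in 8 of 8 knockout arrays. Its adjusted p over all probe sets was 0.136. Adjusted over the list alone it was 0.0134, which made Scd1 the single one of 548 measured list entries to pass in that way, and over all probe sets none passed. Agpat2, an acyltransferase of triglyceride synthesis, differed by 0.24 (SE 0.10) and Scd2 by 0.33 (SE 0.20). Scd1 and Scd2 both lie on chromosome 19, which carries Sfrp5 and whose genes were over-represented among the lowest p-values, as described below. For these 2 genes a response of the pathway and an effect of linkage to the allele cannot be told apart here. The list's camera adjusted p was 0.0661 after quantile normalization, 0.186 without wild-type replicate 7, 0.0501 without knockout replicate 6 and, with the opposite direction, 0.649 with replicates 7 and 8 as the only knockout arrays. Of 20 adipocyte identity genes and adipokines 15 were higher, with a mean of 0.04 (SE 0.05; camera adjusted p = 0.0283, and adjusted p = 0.872 with an estimated correlation). Adipoq, the gene of adiponectin, differed by 0.17 (SE 0.06; limma adjusted p = 0.328), Cd36, a fatty acid transporter, by 0.08, Cebpa by 0.10, Pparg by -0.07 and leptin, Lep, by -0.08. That list did not pass without any 1 of wild-type replicates 2, 4 and 7 or knockout replicates 3, 5 and 6, where its camera adjusted p reached 0.305, nor after quantile normalization (adjusted p = 0.858), with dim probe sets left out (0.0737) or, with the opposite direction, with replicates 7 and 8 as the only knockout arrays (0.784).

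Other genes of adipocyte function showed no shift past the threshold. Lipolysis and lipid droplet genes were higher for 9 of 16 (camera adjusted p = 0.525), with Plin4 at 0.14, Plin1 at 0.16 and Abhd5 at -0.08. Brown and beige adipocyte genes were higher for 8 of 16 (adjusted p = 0.994), with Cox8b at 0.28 (SE 0.17), Prdm16 at -0.14, Otop1 at 0.12 and the uncoupling protein Ucp1 at -0.05 (SE 0.11); their mean was 0.02 and their median -0.01. Insulin signalling genes were higher for 8 of 18 (adjusted p = 0.688), with Pik3ca at -0.14, Akt2 at 0.15 and Tbc1d4 at 0.08. Among 6 genes that track expansion of adipose tissue 2 were higher (adjusted p = 0.694), with Mest at -0.20 (SE 0.24), Bmp3 at -0.16 and Npr3 at -0.06.

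Wnt target genes were higher for 11 of 20 measured members, with a mean log2 difference of 0.02 (SE 0.04; camera adjusted p = 0.583). Axin2, a feedback inhibitor induced by Wnt signalling, differed by 0.21 (SE 0.13; limma adjusted p = 0.639), Ccnd1 by 0.23, Sp5 by 0.20 and Ccn5 by -0.15. Wnt ligands, receptors and the other secreted antagonists were split evenly, 18 higher and 18 lower of 36 (adjusted p = 0.644), with a mean of 0.01 and a median of -0.00. The co-receptor Lrp6 differed by -0.15 (SE 0.07) and the frizzled receptors Fzd8 and Fzd5 by -0.14 and -0.15.

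Markers of macrophages, which gather in fat on a high-fat diet, were higher for 23 of 25 measured genes, with a mean log2 difference of 0.09 (SE 0.19; camera adjusted p = 0.0373, and adjusted p = 0.872 with an estimated correlation). Knockout replicate 8, at 9.61, and wild-type replicate 2, at 9.18, stood above the remaining 13 arrays, at 8.24 to 8.89. Without knockout replicate 8 the list's adjusted p was 0.943 with the opposite direction, and it did not pass without any 1 of wild-type replicates 1, 3, 4 and 7 or knockout replicates 1, 3 and 7 either, with adjusted p up to 0.254, nor after quantile normalization (adjusted p = 0.0783), with dim probe sets left out (0.228) or with array weights (0.147). With replicates 7 and 8 as the only knockout arrays its adjusted p was 7.74e-16, and without these 2 it was 0.359 with the opposite direction. Adgre1, the gene of F4/80, differed by 0.20 (SE 0.20), Cd68 by 0.11 (SE 0.26), Marco by 0.15, Cd14 by 0.15 and Cd163 by -0.22. Cytokine and chemokine genes were higher for 13 of 26 (adjusted p = 0.583), with Ccl5 at 0.26, Ccl2 at 0.11 (SE 0.29), Nlrp3 at -0.16, Ptgs2 at -0.14 and Tnf at -0.10 (SE 0.08). T and natural killer cell markers were higher for 10 of 18 (adjusted p = 0.496; Cd8b1 at 0.22, Gzmb at 0.16, Gzma at -0.14) and B cell markers for 10 of 14 (adjusted p = 0.435; Jchain at 0.32, Cd79b at 0.07, Ms4a1 at -0.08). Neutrophil and mast cell markers were lower for 12 of 14, with a mean of -0.08 (SE 0.04; adjusted p = 0.496) and with Cxcr2 at -0.22, Ngp at -0.16 and Kit at -0.09.

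Mesothelial markers, genes of the sheet of cells that covers visceral fat, had the largest list difference per gene apart from the epididymis list. Of 15 measured genes 14 were higher in the knockout, with a mean log2 difference of 0.32 (SE 0.17), and camera gave adjusted p = 4.31e-06. With an estimated correlation the adjusted p was 0.872, and an exact permutation test of the mean per array gave p = 0.0802. With replicates 7 and 8 as the only knockout arrays the camera adjusted p was 0.0530. Krt19, a keratin, differed by 0.66 (SE 0.28), Muc16, a surface mucin, by 0.65 (SE 0.26) and Upk1b, a uroplakin, by 0.54 (SE 0.22); none of the 15 passed alone. Adipose progenitor and fibroblast markers were higher for 11 of 15, with a mean of 0.09 (SE 0.05; camera adjusted p = 0.0283, and adjusted p = 0.872 with an estimated correlation). Dcn, the gene of decorin, differed by 0.15 (SE 0.06), Lum by 0.20 and Cd34 by 0.12. That list did not pass without any 1 of replicates 1 and 3 of either genotype, where adjusted p ranged from 0.0524 to 0.133, nor after quantile normalization (adjusted p = 0.138), with dim probe sets left out (0.0704) or without knockout replicates 7 and 8 (0.0630). Endothelial markers were lower for 16 of 18, with a mean of -0.08 (SE 0.07; camera adjusted p = 0.0387, and adjusted p = 0.872 with an estimated correlation). Gpihbp1, which anchors lipoprotein lipase on capillaries, differed by -0.15 (SE 0.09), Tie1 by -0.16 and Eng by -0.15. The endothelial list passed in 7 of the 15 fits with 1 array left out. It did not pass without any 1 of wild-type replicates 1, 2, 5, 6 and 7 or knockout replicates 2, 4 and 6, with adjusted p up to 0.376, nor with median centring (adjusted p = 0.0625) or, with the opposite direction, with replicates 7 and 8 as the only knockout arrays (0.649).

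**Figure D2:**
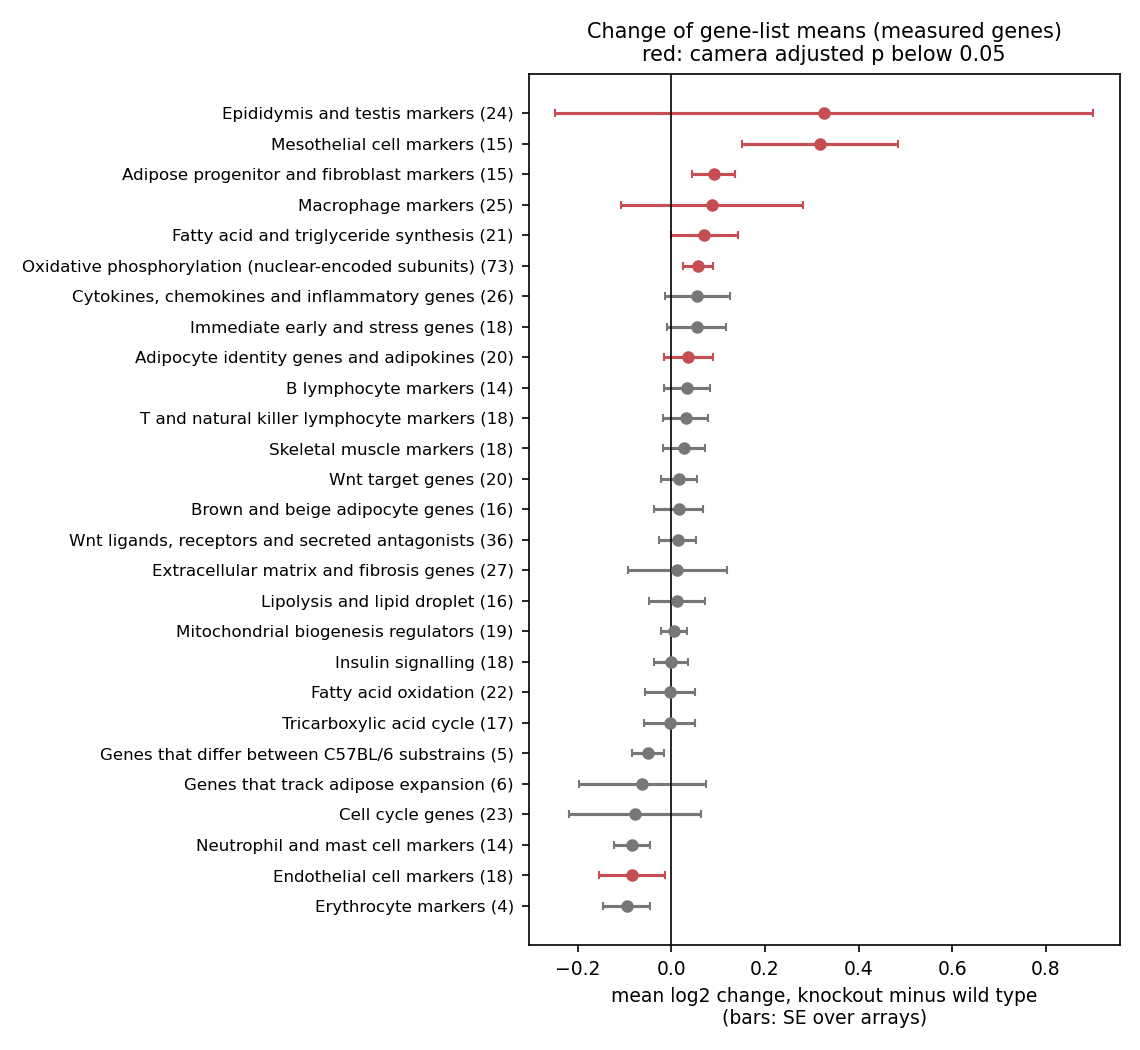
Mean log2 difference, knockout minus wild type (horizontal axis), of each fixed gene list, with the number of measured genes in brackets and bars of 1 SE over arrays; red marks the 8 lists with a camera adjusted p below 0.05 at the preset correlation. The epididymis list has the widest bar (0.33, SE 0.57), and the oxidative phosphorylation list a narrow one (0.06, SE 0.03).

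Epididymis and testis markers, present where a piece of the adjoining organ is taken with the fat, were higher for 18 of 24 genes, with a mean of 0.33 (SE 0.57; camera adjusted p = 0.0373, and adjusted p = 0.872 with an estimated correlation). The list mean was 9.92 in knockout replicate 2 and 8.10 in wild-type replicate 4, against 5.87 to 7.12 in the other 13 arrays. Gpx5, Lcn9 and Cst11, secreted proteins of the epididymis, differed by 1.15 (SE 0.91), 1.08 (SE 0.75) and 0.86 (SE 0.70), and without knockout replicate 2 by 0.26, 0.36 and 0.15. Without knockout replicate 2 the list's adjusted p was 0.965, and it did not pass without any 1 of wild-type replicates 1, 3, 5 and 7 or knockout replicate 3 either, with adjusted p up to 0.180, nor with dim probe sets left out (0.228), with array weights (0.105) or, with the opposite direction, with replicates 7 and 8 as the only knockout arrays (0.0530). Knockout replicate 2 and wild-type replicate 4 also had the lowest median correlation with the others, 0.969 and 0.972. With both left out, a choice made after seeing the data, no probe set passed limma's adjusted threshold, 2963 had an unadjusted p below 0.05, and the Sfrp5 difference was -1.17 (adjusted p = 0.119). Skeletal muscle markers were higher for 11 of 18 (camera adjusted p = 0.438; Tnni2 at 0.21, Acta1 at 0.33, Myh1 at -0.12). The 4 measured erythrocyte genes, too few for the list test, were all lower, Alas2 by a log2 difference of -0.14, Slc4a1 by -0.13 and Car1 by -0.11, and an exact permutation test of their mean gave p = 0.0723.

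**Figure D3:**
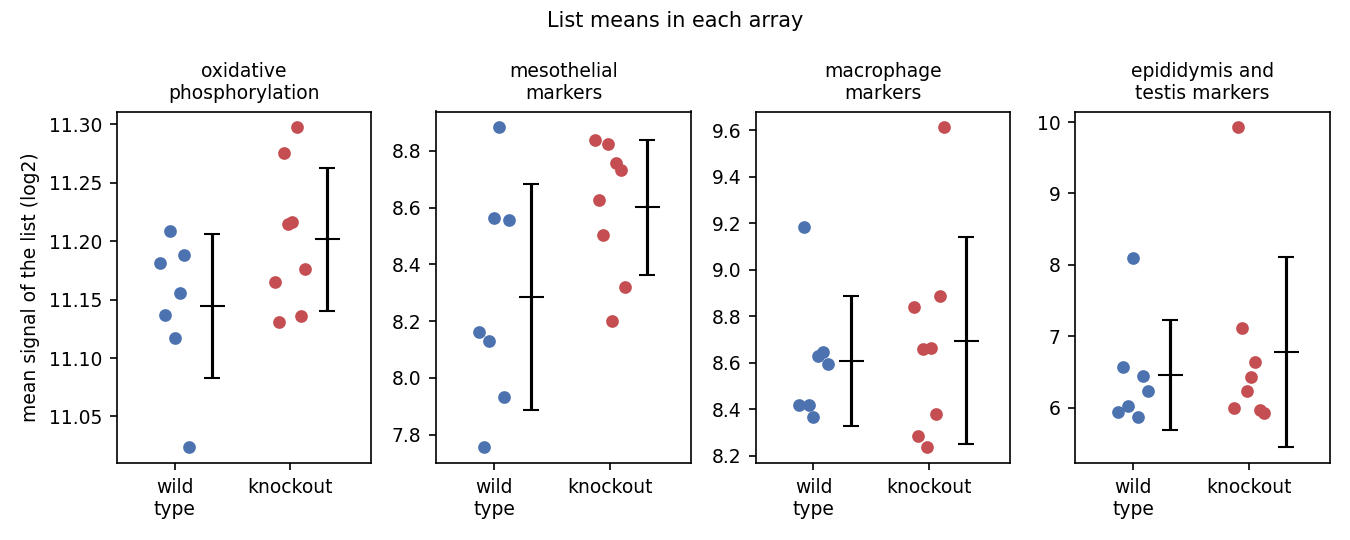
Mean log2 signal of 4 gene lists (vertical axis, its own scale per panel) in each of 7 wild-type and 8 knockout arrays, with the mean and SD of each genotype beside its points. Knockout replicate 2, at 9.92, and wild-type replicate 4, at 8.10, stand apart in the epididymis and testis panel.

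Of the remaining lists, extracellular matrix genes were higher for 13 of 27 (camera adjusted p = 0.227), with a mean of 0.01 and a median of -0.00; Mmp2, a matrix protease, was at 0.26 (SE 0.10) and Tnc at -0.36 (SE 0.16). Immediate early and stress genes, a sign of handling, were higher for 12 of 18 (adjusted p = 0.0939; Zfp36 at 0.19, Jun at 0.15, Egr2 at 0.54). With 1 array left out that list's camera adjusted p ranged from 0.00963, without knockout replicate 6, to 0.527, without knockout replicate 8. Cell cycle genes were lower for 17 of 23 (adjusted p = 0.344; Ccne1 at -0.16, Kif20a at -0.12, Kif11 at -0.35). Of 5 genes that differ between C57BL/6 substrains all were lower (adjusted p = 0.532). Their mean was 8.41 in knockout replicate 7 and 8.33 in knockout replicate 8, against 8.50 to 8.58 in the other 13 arrays, and without these 2 the direction turned (adjusted p = 0.915). Nnt, part of which is deleted in C57BL/6J mice, differed by -0.10 (SE 0.09), Glo1 by -0.09 and Wdfy1 by -0.05.

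Genes on chromosome 19, which carries Sfrp5, were over-represented among the genes with the lowest p-values. Of the 100 named genes with the lowest p, 13 lie on chromosome 19, against 678 of 19919 genes, or 3.40%, in the background, an odds ratio of 4.30 (95% interval 2.19 to 7.80; Fisher's exact test, two-sided, p = 3.43e-05). Without Sfrp5 itself the count was 12 of 99 (Fisher's exact p = 0.000134). In the gene order of the GRCm38.p6 annotation, used here for neighbours only since the build of the array values is not given in the sources used here, 8 of the other 12 lie within 73 measured genes of Sfrp5. These are Pyroxd2 (0.32), Pgam1 (0.18), Scd1 (0.21) and As3mt (0.44), higher in the knockout, and Arhgap19 (-0.53), Cutc (-0.34), Cyp2c38 (-0.31) and Arl3 (-0.20), lower. Farther away lie Rnaseh2c (0.26), Tut1 (-0.32), Rln1 (-0.32) and Ric1 (-0.24). The 12 genes other than Sfrp5 did not pass the adjusted threshold by themselves. Those of them outside the rule for named genes are named for this count after their values were seen. The count ranged from 11 to 15 with any 1 array left out, and was 8 (Fisher's exact p = 0.0208) with replicates 7 and 8 as the only knockout arrays.

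**Figure D4:**
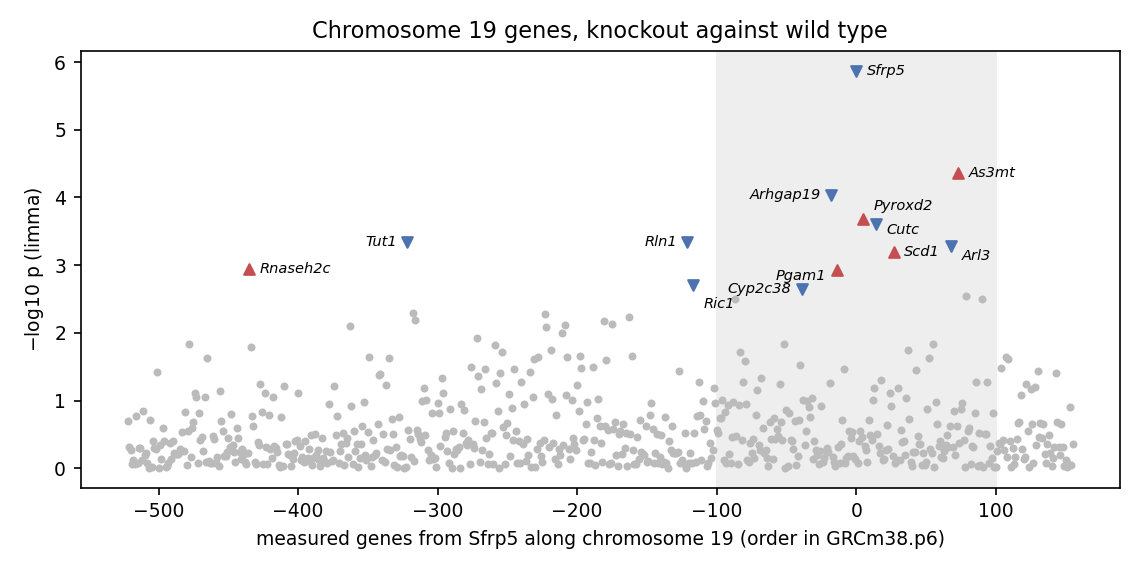
Minus log10 of limma's p for each measured gene of chromosome 19 (vertical axis) against its distance from Sfrp5 in measured genes, in GRCm38.p6 order (horizontal axis). Coloured triangles are the 13 genes among the 100 with the lowest p, pointing up where higher and down where lower in the knockout, grey points are other genes, and the shaded band, a width chosen after the positions were seen, holds the 100 genes on each side, where 8 of the other 12 triangles lie.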

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

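A value was listed here where 1 array of a genotype lay far from the others of that genotype, by Dixon's criterion at its 95% critical value, applied to the 114 named genes and the 27 list means. Of 282 groups tested, 28 met it, or 9.93%, where chance gives about 1 in 20. Values are log2 signals, and the range of the remaining arrays of the same genotype follows each.

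Knockout replicate 2 accounted for 6 of them. It was high in the epididymal genes Gpx5 (12.54; others 4.62 to 6.66), Lcn9 (12.23; 5.88 to 7.57) and Cst11 (12.44; 6.44 to 7.23) and in the mean of the epididymis and testis list (9.92; 5.93 to 7.12). It was low in Cox8b (9.56; 10.12 to 10.58) and Eng (7.30; 7.63 to 7.87). Wild-type replicate 4 accounted for 4, high in the epididymis and testis mean (8.10; 5.87 to 6.57) and low in the endothelial mean (8.57; 8.85 to 9.02), Lrp6 (9.69; 9.94 to 10.02) and Pik3ca (9.25; 9.45 to 9.53).

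Immune genes stood apart in other arrays. Wild-type replicate 2 was high in the macrophage mean (9.18; 8.37 to 8.65), Cd68 (10.66; 9.52 to 9.99), the cytokine and chemokine mean (7.50; 7.17 to 7.29) and the early response gene Egr2 (8.94; 7.93 to 8.25), and low in Wdfy1 (7.36; 7.51 to 7.62). Knockout replicate 8 was high in the macrophage mean (9.61; 8.24 to 8.89) and low in Cxcr2 (4.21; 4.60 to 4.93). Wild-type replicate 5 was high in the mesothelial genes Upk1b (9.84; 8.01 to 8.62) and Muc16 (9.01; 7.08 to 7.71).

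Adipocyte and other genes make up the rest. Wild-type replicate 7 was low in the lipid droplet gene Plin1 (10.16; 10.69 to 11.03) and in Tbc1d4 (8.11; 8.38 to 8.55) and high in Lcn9 (6.88; 5.79 to 6.07). Wild-type replicate 1 was high in Abhd5 (11.74; 11.46 to 11.57) and in the cyclin gene Ccne1 (7.82; 7.28 to 7.41). Knockout replicate 1 was low in the mitochondrial gene ND3 (12.42; 12.72 to 12.90) and in Scd1 (13.14; 13.26 to 13.36), knockout replicate 3 high in Gabpa (10.15; 9.91 to 9.98), and knockout replicate 7 low in the dim gene Olfr270 (4.56; 4.72 to 4.82).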

How the results depend on the processing

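The fits without the least correlated array of each genotype, the exact permutation of list means, and the position test under other settings, apart from the lowest 50 and 200 genes, were chosen after seeing the data; the others were fixed before. The 12 probe sets past the threshold kept their direction in every fit run on these arrays, apart from 1 that the filter on dim probe sets removed. They were picked from these same arrays, so the kept direction adds no separate support. The number of probe sets past the threshold moved. Quantile normalization gave 6, median centring 7, the filter on dim probe sets 26, an intensity trend with a robust prior 48, and array weights 25. No probe set passed limma's adjusted threshold with description numbers of 640 or higher only (7 wild-type and 2 knockout arrays), where 3392 had an unadjusted p below 0.05, nor without the least correlated arrays, where 2963 did. Without knockout replicates 7 and 8 there were 2. An unadjusted p below 0.05 gave 3544, an adjusted p below 0.1 gave 98, and adjustment over named genes alone gave 1. With 1 array left out the count ranged from 0 to 133. Sfrp5 stayed lower throughout, at -0.93 (adjusted p = 0.316) with numbers of 640 or higher, at -1.17 (adjusted p = 0.119) without the least correlated arrays, and from -1.29 to -1.13 with 1 array left out (adjusted p from 0.00413 to 0.0670); over all alternatives its adjusted p ranged from 0.00413 to 0.316. Fewer arrays may be part of the reason for the lost calls, although the count of probe sets rose to 133 in 1 such fit. The cause was not tested. The number of gene lists past the threshold went from 8 to 3 with quantile normalization, 4 with the dim filter, 0 with an estimated correlation, 0 with fry and 0 with an exact permutation of list means, and ranged from 3 to 8 with 1 array left out. The count of chromosome 19 genes among the 100 passed Fisher's exact test under every alternative, from 8 (p = 0.0208, numbers of 640 or higher) to 15, with 10 of the lowest 50 and 19 of the lowest 200. Dim probe sets limit the rest: signal over background was not in the values used.

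The labels do not state that the replicate numbers pair the mice, and the values gave no clear sign of it. Deviations of arrays with the same number correlated between -0.117 and 0.248, above 0.1 in 3 of 7 pairs, and 0 of 7 wild-type arrays correlated best with their own number. With the replicate number as a block (7 and 7 arrays, without knockout replicate 8) limma called 0 probe sets, 3098 had an unadjusted p below 0.05, and Sfrp5 differed by -1.28 (adjusted p = 0.3001).

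Directions turned for results that mostly lay near 0, and the cause was not tested. In what follows a list has camera's adjusted p unless another test is named, and a gene its log2 difference. With quantile normalization the lists that turned were tricarboxylic acid cycle (0.409), fatty acid oxidation (0.520), lipolysis (0.858) and insulin signalling (0.913). Brown and beige genes turned with median centring (0.997), the dim filter (0.989), ranks (0.912), fry (0.990) and without knockout replicates 7 and 8 (0.936). Fatty acid oxidation turned with the dim filter (0.989). With fry the Wnt ligand, tricarboxylic acid, fatty acid oxidation and insulin lists turned (0.990 each), and with the exact permutation the last 3 (0.961 each). Without the least correlated arrays mitochondrial biogenesis (0.858) and tricarboxylic acid cycle (0.9996) turned. With the replicate block macrophage (0.934), cytokine (0.986) and extracellular matrix lists (0.945), Cd68 (-0.0773) and Ccl2 (-0.0905) turned. Without knockout replicates 7 and 8 so did macrophage (0.359), cytokine (0.412), matrix (0.361) and substrain lists (0.915), Cd68 (-0.15) and Ccl2 (-0.18).

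With numbers of 640 or higher, the setting with 2 knockout arrays, the oxidative phosphorylation (0.391) and mesothelial lists (0.0530) kept their direction but no longer passed, the progenitor list still passed (0.00814) and the macrophage list had 7.74e-16. The lists that turned were Wnt ligands (0.973), mitochondrial biogenesis (0.342), tricarboxylic acid cycle (0.00154), fatty acid oxidation (0.158), fatty acid and triglyceride synthesis (0.649), adipocyte identity (0.784), insulin signalling (0.264), endothelial (0.649), epididymis (0.0530), cell cycle (2.03e-05) and adipose expansion (0.272). The genes were Dld (-0.0296), Pdhb (-0.000266), Tbc1d4 (-0.0370), Jchain (-0.21), Tie1 (0.0180), Lcn9 (-0.0521), Gpx5 (-0.26), Cst11 (-0.13), Ccne1 (0.0482), Kif11 (0.29), Mest (0.33), Ppargc1a (-0.16), Tfam (-0.00185), Ucp1 (0.0464) and Lep (0.24).

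With 1 array left out, ranges of results that turned at least once were 0.470 to 0.978 for mitochondrial biogenesis, 0.260 to 0.987 for tricarboxylic acid cycle, 0.254 to 0.953 for fatty acid oxidation, 0.158 to 0.939 for lipolysis, 0.507 to 0.989 for brown and beige genes and 0.507 to 0.939 for insulin signalling. They were 0.000221 to 0.943 for macrophages, 0.248 to 0.910 for cytokines, 0.0154 to 0.9497 for cell cycle and 0.507 to 0.984 for adipose expansion. The matrix list (0.00458 to 0.926) and the substrain list (0.278 to 0.885), which turned in other settings, kept their direction with 1 array left out. The genes ranged from -0.0370 to 0.18 for Ppargc1a, -0.10 to 0.0216 for Ucp1, -0.14 to 0.0120 for Lep, -0.0773 to 0.25 for Cd68 and -0.0905 to 0.29 for Ccl2.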

Other observations

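Of the tests below, those on other splits of the arrays and on the signal level were written before their results were seen; the others were chosen after. For mesothelial against endothelial markers, the reading of the test was also amended after its value was seen, from going with a lower share of fat cells to leaving it open, and a test against 6 other lists was added after their means were seen.

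Ribosomal protein genes, a group outside the fixed lists that was picked after the oxidative phosphorylation list was seen, were higher in the knockout for 48 of 57 genes, with a mean log2 difference of 0.08 (SE 0.03; exact permutation p = 0.0148). After quantile normalization 34 of 57 were higher, with a mean of 0.02 (exact permutation p = 0.343). The mean of the oxidative phosphorylation list minus that of the ribosomal protein genes was -0.02 (SE 0.05). Of the genes encoded by mitochondrial DNA, COX2 differed by 0.27 (SE 0.07; limma adjusted p = 0.168) and ND3 by 0.33, and after quantile normalization by 0.20 and 0.25. MicroRNA genes lay on the lower side, with 74 of 297 higher and a median of -0.07, and 89 higher after quantile normalization; their median level, 5.80, was dim.

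Most of the differences with a low p lay in probe sets without a gene symbol. Of 12147 such probe sets 167 had p below 0.001, of which 137 were higher in the knockout, while of 21789 probe sets with 1 symbol 53 did, of which 32 were higher. Across 100 of the 6435 splits of the 15 arrays into 7 and 8, the real one included, no other split gave more than 50 unnamed probe sets, whereas for named ones 3 of the 100 gave as many as the real split and the highest other gave 92. What these unnamed probe sets measure was not analysed here, and control probe sets may be among them.

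The same 100 splits were set against 3 results. For the 12 probe sets past the threshold, 1 of 100 splits, the real one, gave as many, and the highest other gave 1. This makes chance unlikely, but 100 splits cannot exclude it, and the targeted gene Sfrp5 is itself among the 12. For the 8 gene lists, 39 of 100 splits gave as many and the highest other gave 15, so chance was not excluded. For the 13 genes of chromosome 19 among the 100 with the lowest p, 1 of 100 splits gave as many and the highest other gave 10. Chance is unlikely here too without being excluded, and Sfrp5 is among the 13. No comparison of splits can separate genotype from anything aligned with it, such as the array positions, where all wild-type arrays come first.

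A hypothesis for the genes of chromosome 19 is that variants linked to the Sfrp5 allele, carried along from the chromosome on which the allele arose, may alter their transcripts or their probes' binding. The excess of chromosome 19 among the 100 genes (Fisher's exact p = 3.43e-05) is what linkage needs, and that without Sfrp5 itself (Fisher's exact p = 0.000134) argues against an effect of Sfrp5 loss without regard to position as the whole cause. That 8 of the other 12 genes lie close to Sfrp5 was seen before any width was chosen, so no p is given for it. Mismatched probes lower a signal, yet genes higher in the knockout were also more frequent on chromosome 19 (5 of 677 against 39 of 19241, Fisher's exact p = 0.0163), which argues against mismatch on the knockout allele as the whole cause of the excess. For the genes lower in the knockout (7 of 677 against 48 of 19241, Fisher's exact p = 0.00250), mismatch and lower transcript cannot be told apart, as the probe sequences were not used here. An effect of Sfrp5 loss on neighbouring genes stays open, as no mice with the allele on another background were compared.

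The higher oxidative phosphorylation genes may reflect the scaling of the arrays in part. After quantile normalization the list mean went from 0.06 (SE 0.03) to 0.00598 (SE 0.03), and its call was lost. The list's median fell from 0.06 to 0.00550, and the median of random lists matched on level fell about as far, from 0.03 to -0.03, so the list moved down with genes of its level. Even so, the list's median stood at the 99.93th percentile of 10000 random lists matched on level, and at the 99.76th after quantile normalization. The random lists hold genes that need not vary together, whereas the estimated correlation between genes of this list was 0.305. The percentile leaves out this shared variation, so it cannot by itself exclude a level trend as the whole cause. An exact permutation of the list mean gave p = 0.0987, so differences between mice that these genes share stay open, as does an effect of the genotype.

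The higher mesothelial markers may be a matter of which part of the pad was taken, of more mesothelial RNA in the knockout, or of chance, since an exact permutation test of the list mean gave p = 0.0802. Epididymal tissue carried along was probed by leaving out the array of each genotype highest in the mean of the epididymis and testis list. The mean difference was then 0.36, against 0.32 with these arrays, so these 2 arrays did not make the difference. Smaller amounts of such tissue in the other arrays were not tested and stay open. A lower share of fat cells would raise other cell types alike, yet the endothelial mean was lower and the difference between the lists was 0.40 (SE 0.20; exact permutation p = 0.0687). The mean of 6 other lists of non-fat cells, immune, progenitor and endothelial, differed by 0.01 (SE 0.05), or 0.30 (SE 0.19) less than the mesothelial mean (exact permutation p = 0.128). Of 20 adipocyte identity genes, which fewer fat cells would lower, 15 were higher (mean 0.04, SE 0.05). The 6 lists together showed no rise near 0.32, but their mean joins lists that differed in direction. Macrophage and progenitor markers were at 0.09, T and B cell lists at 0.03, and endothelial and neutrophil and mast cell markers at -0.08. The mesothelial rise itself has an SE of 0.17, and the permutation test did not separate it from the 6 lists. These values therefore cannot decide on a lower share of fat cells, which stays open. After quantile normalization 14 of 15 mesothelial genes were still higher. Sampling site and genotype effects were not tested against each other.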
